A study of Rattus norvegicus with 6 samples.

How the data were processed

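Total RNA of differentiated rat trophoblast stem cells was taken from 3 wild type and 3 Cited2 null samples. Per the labels, RNA was isolated with TRIzol, libraries were made with Illumina TruSeq kits and read on a HiSeq2000 as 100-base pairs, and the reads were mapped to the Rnor_6.0 assembly with CLC Genomics Workbench 20.0.4. The annotation release, the settings for reads that map to several places and the strand of the libraries are not given in the sources used here. The deposited table gives RPKM, reads scaled to exon length and to mapped reads, for 29107 transcripts under 22243 gene names, of which 17258 have 1 transcript. The authors' table also gives, for the groups as its columns are headed, a signed fold change of the mean RPKM (a score), a signed fold change of the EDGE test (a score) and that test's p-value and FDR.

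The descriptions of the C samples state that their titles were exchanged. Samples were grouped by these descriptions, before the data were examined. Column headings in the table follow the titles, and the authors' fold change equals the ratio of means by heading in 100% of 21999 transcripts with both means above 0, and by corrected genotype in 2.52%, to a relative tolerance of 1e-06. The column headings also place the library called null replicate C here in a sequencing lane of its own. That lane holds 1 library, so no value within lanes can be had for it.

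RPKM values of the transcripts of a gene name were summed, a step of this work and not of the authors. The steps between RPKM values gave the number of mapped reads of each library and the reads of each transcript, whole to a tolerance of 1e-06 reads in 100% of values. The mapped reads numbered between 25602047 and 31838945. A count of 3 reads, taken as the floor, is 0.0942 to 0.117 RPKM in a transcript of 1000 bases, depending on the library. Floors cover counting error only. Libraries of 1 genotype were checked for duplicates by the chi-square per degree of freedom of their reads, which lay between 7.07 and 15.2 where copies would give about 1 or less.

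Genes at 1 RPKM or more in at least 3 libraries were tested. The model was limma-trend with robust eBayes on log2(RPKM + 0.1), with genotype as the only term and null minus wild type as the direction. A gene was called past a Benjamini-Hochberg FDR of 0.05. The design fixed before the data were examined named a count test for a table of counts and this limma test for a table of RPKM. On simulated data, with reads drawn from a negative binomial distribution at the real depths and mean levels and 200 genes changed, 10760 genes entered the step. The limma-trend test found 47 of 50 genes changed by 1.5-fold, 50 of 50 at 2-fold, 50 of 50 at 4-fold and 49 of 49 at 8-fold, and called 11 of 10561 unchanged genes. The limma-voom alternative found 92% at 1.5-fold and 100% at 2-, 4- and 8-fold, and called 8 unchanged genes. The simulation used 1 fixed dispersion for all genes and drew genes independently, whereas neighbouring genes moved together in the data. It therefore checks that the fits work and does not give their error rates in these data.

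Gene lists, 23 in number, were written before the data were examined: stem-state trophoblast, prolactin family, giant cell and placental cathepsin, invasive trophoblast, spongiotrophoblast and glycogen cell, syncytiotrophoblast and labyrinth, hypoxia response, interferon response, antigen presentation, CITED2 partners and homologues, proliferation, steroidogenesis, cholesterol synthesis, matrix proteolysis and its inhibitors, imprinted genes, unfolded protein and integrated stress response, fibroblast and mesenchyme, endothelium, macrophage and blood cell, extraembryonic endoderm, epiblast and pluripotent cell, X inactivation and Y-linked, and mitochondrially encoded genes. For 22 of them camera (two-sided, preset correlation 0.01) compared the list with the other tested genes, with adjusted p over the 22. Camera with an estimated correlation and fry were run beside it; fry tests whether a list's genes move on balance one way and makes no comparison with other genes. The macrophage and blood cell list had 2 tested genes and no set test. Some genes are in several lists.

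The genes named are Cited2; the 12 with the most positive and the 12 with the most negative fold change among those past the FDR and 2-fold, with non-overlapping groups, a mean of 10 RPKM or more in the higher genotype and a symbol that is not a placeholder; and up to 2 per list and direction with the smallest p. This rule was fixed before the data were examined. Prl3b1, Prl3d1, Prl7a4, Mxi1, Ppp1r3c, Adm, Pgk1, Eno1, Ldha, Vegfa, Hif1a, Epas1, Hand1, Cdx2 and Kdm5d were named after their values were seen. The same holds for Igf2, Plau, Plaur, Plat, Serpine2, Prl2a1, Flt1, Pygl, Ugp2, Gys1, Cyp11a1, Gcm1, Pdgfra, LOC100911713, the class I heavy chain genes, the further Y-linked genes, the genes read in 1 genotype alone and the genes that mark segments or chromosomes.

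Genes were placed by RefSeq symbols in the order of the GRCr8 assembly, for 9854 of the tested genes. The 10 genes around a gene were 5 on each side beyond the 2 nearest, and fold changes were limited to 2 on the log2 scale for this step. Segments of at least 15 neighbouring genes came from binary segmentation of each chromosome, in which a split needed a step of at least 6 standard errors, and those with a median of 0.5 or more on the log2 scale in either direction are reported. In a shuffled order with 90 neighbouring genes raised by 1 on the log2 scale, the method recovered 90 of 90. Recovery of a stretch as short as 15 genes was not tried.

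The alternatives were a pseudocount of 1, no filter, a mean of 5 RPKM or more, the replicate letter as a block, leaving out each library, the C libraries grouped by title, neither C library, a 2-fold threshold, camera with an estimated correlation and fry. A further 4 were added after the data were seen: single transcripts, median-of-ratios scaling, limma-voom on the recovered reads, and subtraction of the median fold change of the 50 nearest genes. Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The genome sequence was not used here, so GC content was not tested.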

Results

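RNA was measured in rat trophoblast stem cells, the cells of the early embryo that give rise to the placental trophoblast, after 12 days of differentiation without the growth factors that hold them in the stem state. The cells came from wild type and Cited2 null blastocysts of the Holtzman Sprague-Dawley strain, with 3 libraries for each genotype, called replicates A, B and C. The labels state that the C libraries were exchanged between the genotypes, and each library was placed in the genotype that its corrected description gives. The values are RPKM, summed here over the transcripts of each gene name, and the depth was recovered from their steps. The wild type libraries held 26414694, 26896556 and 28992070 mapped reads in replicates A, B and C, and the null libraries 25602047, 31838945 and 29861152. Between 10478 and 10688 genes per library reached 1 RPKM. Across genes, the Pearson correlation between libraries of 1 genotype was at least 0.987, and between genotypes at most 0.917. Genes are not independent replicates, and no test was made of these correlations. RPKM values are given as mean ± SD of 3 libraries. Fold changes are differences of log2(RPKM + 0.1), null minus wild type, with the limma standard error (SE), and adjusted p is limma's Benjamini-Hochberg value.

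The targeted gene was read first. CITED2 is a transcriptional co-regulator that binds the acetyltransferases CBP and p300 and competes with hypoxia-inducible factors for them. Cited2 stood at 428, 422 and 413 RPKM in wild type replicates A, B and C and at 12.9, 14.3 and 12.3 RPKM in the null replicates. The mean was 421 ± 7.33 RPKM in wild type and 13.2 ± 1.04 RPKM in null cells, a log2 fold change of -4.99 (SE 0.0663, adjusted p = 1.28e-10). The labels do not say which part of the gene was deleted, so the position of the remaining reads relative to the deletion is unknown. In the authors' deposited table the C libraries keep their exchanged headings, and there Cited2 has a ratio of means of -1.96 and, from the EDGE test, a fold change of -2.004 with a p of 0.406 and an FDR of 1.

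The comparison of null with wild type cells addresses what differentiated rat trophoblast cells express without CITED2, in a series whose title concerns deep placentation, the entry of trophoblast far into the uterine wall. Null cells held more RNA of the prolactin family hormones of the placenta and of genes of the hypoxia response, and less of most enzymes of cholesterol synthesis. As sets these lists passed with a preset correlation between genes but not with an estimated one (adjusted p = 0.404, 0.404 and 0.752). Fry, which makes no comparison with other genes, passed for each (adjusted p = 1.03e-04, 6.67e-04 and 0.00683). Genes of matrix proteolysis and its inhibitors, taken as 1 list, were mostly higher, although Mmp9 was among the genes that fell furthest. With a preset correlation and grouping by description, that list passed camera in 8 of 16 settings. Markers of spongiotrophoblast and glycogen cells were mostly higher and those of syncytiotrophoblast mostly lower, but neither list passed camera's test against the other genes (adjusted p = 0.146 for each) except when low values were not filtered. Of 9 genes of the Y chromosome named in the table, 3 were read in all 3 null libraries and scarcely or not at all in wild type. Neighbouring genes on the chromosomes also shifted together. The labels separate genotype from cell line in 0 libraries. For all of these results, loss of CITED2 and other differences between the lines therefore cannot be told apart.

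Of 10861 genes tested, 6744 passed an FDR of 0.05 in limma, which is 62.1%. Of these, 3123 were higher and 3621 lower in null cells. The higher share was 46.3%, but 50.9% with median-of-ratios scaling and 50.7% after subtraction of the neighbourhood median. Which direction led thus depended on the processing. An additional 2-fold threshold left 1234 genes, 710 higher and 524 lower, and a 4-fold threshold left 222 higher and 100 lower. The 3 libraries of 1 genotype all lay above the 3 of the other for 7411 genes, or 68.2% of those tested, where chance gives 10%. The median log2 fold change of all tested genes was -0.04. Nothing in the labels says whether the 3 libraries of a genotype came from separate lines or cultures, so the p-values measure the spread between these libraries only. In the authors' deposited table, whose groups keep the exchanged headings, 1 transcript passed an FDR of 0.05 and 20 had a p under 0.05.

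**Figure D1:**
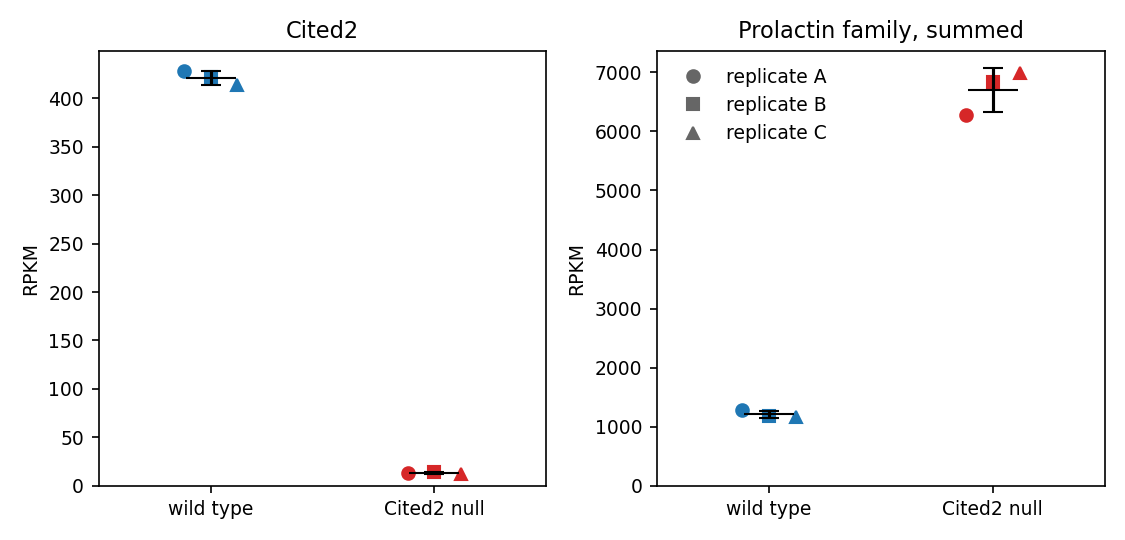
RPKM of Cited2 (left) and the summed RPKM of the prolactin family (right) in each library, by genotype. Bars give the mean and SD of 3 libraries; Cited2 fell from 421 to 13.2 RPKM and the family sum rose from 1211 to 6700 RPKM.

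The prolactin family is a cluster of hormone and cytokine genes that trophoblast cells of rodents secrete into mother and fetus. All 15 tested members rose in null cells, 15 also when adjusted over the list alone, and 14 of them by 2-fold or more. Prl4a1, a hormone that acts on uterine natural killer cells, rose from 170 ± 15.3 to 2422 ± 295 RPKM (log2 fold change 3.83, SE 0.108, adjusted p = 1.77e-08). Prl8a9 rose from 24.2 ± 3.02 to 300.5 ± 41.5 RPKM (log2 fold change 3.62). Prl7b1, which marks invasive trophoblast, rose from 0.306 ± 0.04 to 6.21 ± 1.42 RPKM. The placental lactogens Prl3b1 and Prl3d1 rose by 2.62 and 2.00 on the log2 scale. The smallest change was that of Prl7a4, at 0.63. The summed RPKM of the family was 1211 ± 59.0 in wild type and 6700 ± 371 in null cells. The list's mean log2 fold change was 2.80, and camera with a preset correlation of 0.01 gave it an adjusted p of 7.21e-09, and an adjusted p of 0.404 with an estimated correlation. Members are alike in sequence, so values of single members may include reads of others. Of the 15 members, 14 sit together in 1 stretch of the rat genome and make up all but 1 gene of the segment from Prl5a2 to Mrs2 (median 2.72), which is 1 of the 4 segments of neighbouring genes that shifted together.

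The hypoxia response list holds genes that hypoxia-inducible factors raise, many of them for glycolysis and collagen hydroxylation. Of 31 tested members, 20 rose, none fell and 11 did not pass, and 9 of the 20 changed by 2-fold or more. Adjusted over the list alone, 20 rose and 1 fell, Mxi1 at -0.28. P4ha1 and P4ha2, subunits of the enzyme that hydroxylates collagen, rose from 65.4 ± 4.84 to 178 ± 10.2 RPKM and from 21.4 ± 0.785 to 51.8 ± 3.2 RPKM. The log2 fold changes were 1.44 and 1.27, each with an adjusted p of 5.38e-07. Adm rose from 0.415 to 5.81 RPKM and Ppp1r3c from 0.0751 to 2.14 RPKM, the latter from below the level that 3 reads give in a 1000-base transcript, so that the size of its fold change depends on the pseudocount. The glycolytic genes Pgk1, Eno1 and Ldha rose by 0.77, 0.68 and 0.22. Vegfa did not pass, with a log2 fold change of -0.26 and an adjusted p of 0.174. The list's mean was 0.68 and its median 0.39, with a camera adjusted p of 4.20e-05, and an adjusted p of 0.404 with an estimated correlation. None of its tested members lay in a shifted segment of neighbouring genes. Those segments hold only 1.38% of the placed genes, and most other lists had no member in them either. The absence thus says little about smaller regional shifts.

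**Figure D2:**
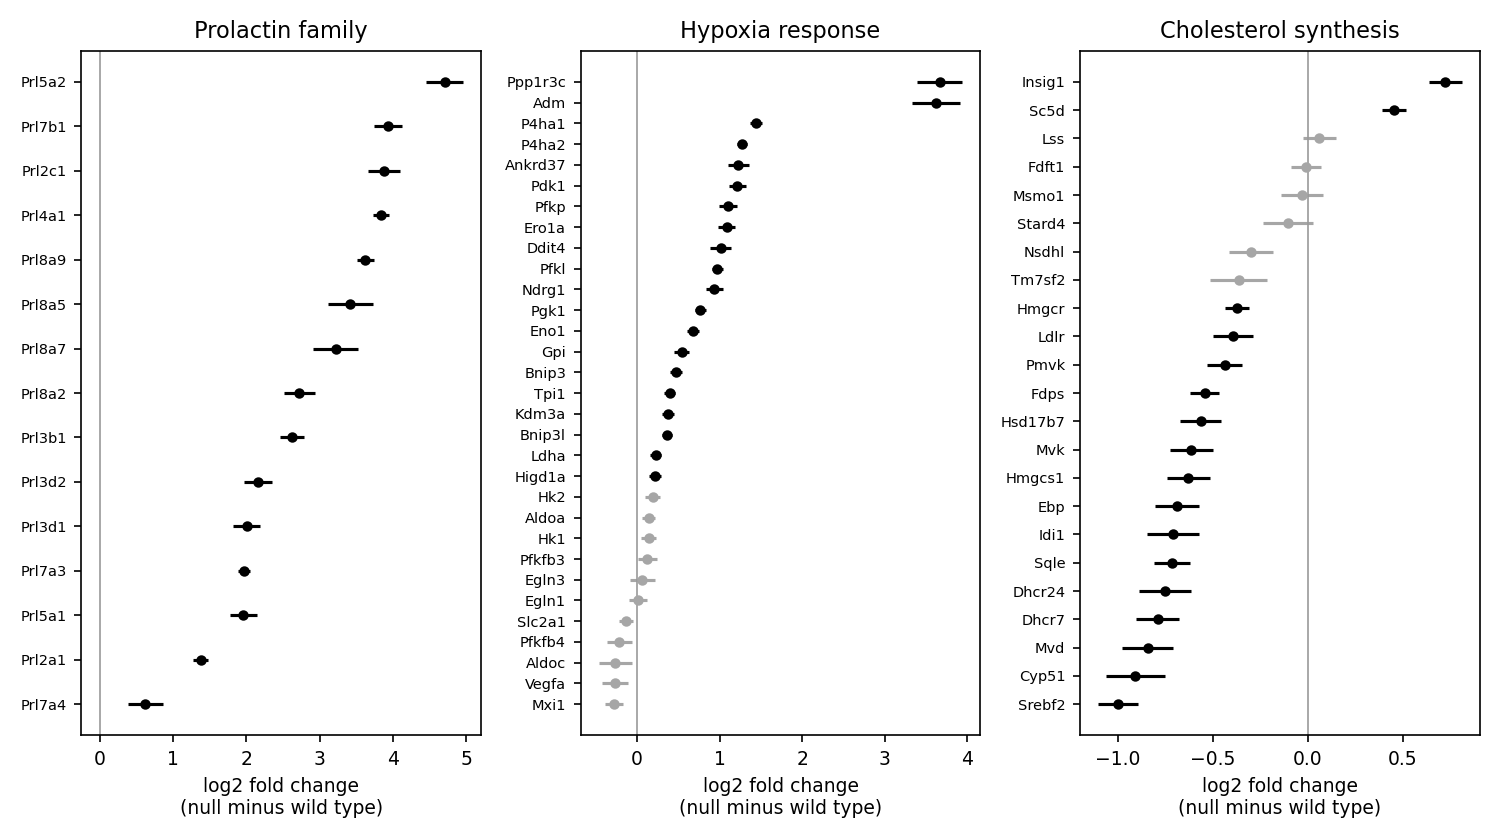
Log2 fold change (null minus wild type) of each tested gene of 3 lists, with the limma standard error as bar; black points passed an FDR of 0.05 over all genes and grey points did not. All 15 prolactin members, 20 of 31 hypoxia members and 2 of 23 cholesterol members were higher, and 15 of the 23 cholesterol members were lower.

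The partners and homologues of CITED2 were mostly lower. Of 15 tested, 2 rose, 9 fell and 4 did not pass, and adjusted over the list alone 2 rose and 10 fell. Cited1, the homologue of the same family, fell from 11.6 ± 0.145 to 4.35 ± 0.521 RPKM (log2 fold change -1.40), and it lies in a stretch of genes from Kif4a to Dmrtc1a with a median of -0.64. Arnt, the partner of the hypoxia-inducible factors, fell by 0.60, and was at -0.23 after the neighbourhood median was subtracted. Hif1a fell by 0.48 and Epas1 by 0.89. Lhx2 and Pparg rose by 0.46 and 0.59, and Lhx2 was at 0.25 after that subtraction and Pparg at 0.36 with neither C library (adjusted p = 0.0439). Its mean was -0.32, and camera's adjusted p was 0.146.

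Cholesterol synthesis was lower in null cells: of 23 tested genes, 2 rose, 15 fell and 6 did not pass, and adjusted over the list alone 2 rose and 17 fell. Srebf2, which encodes the transcription factor that drives the pathway, fell from 29.6 ± 3.41 to 14.7 ± 1.61 RPKM (log2 fold change -0.998, adjusted p = 4.02e-05), and was at -0.59 after the neighbourhood median was subtracted. Sqle, the squalene epoxidase, fell by 0.72. Sc5d rose by 0.45, and Insig1, which restrains the pathway, rose by 0.73. None of the 23 changed by 2-fold past the threshold. On average the pathway stood at -0.41, with a camera adjusted p of 0.0186, and an adjusted p of 0.752 with an estimated correlation. With genes at a mean of 5 RPKM or more, the mean was -0.40 and the camera adjusted p 0.136, and the other alternatives with a preset correlation and grouped by description stayed below 0.05. Steroidogenesis, which uses cholesterol, moved both ways. Of its 13 tested genes, 4 rose, 8 fell and 1 did not pass, with the same numbers adjusted over the list alone, and camera's adjusted p was 0.486. Cyp17a1, the enzyme of androgen synthesis, fell from 11.7 ± 1.62 to 0.243 ± 0.0458 RPKM (log2 fold change -5.10). Fdxr fell from 18.7 ± 2.19 to 6.3 ± 1.13 RPKM. Star, which carries cholesterol into mitochondria, rose from 5.48 ± 1.41 to 32.6 ± 5.89 RPKM, and Scarb1 rose by 0.79.

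**Figure D3:**
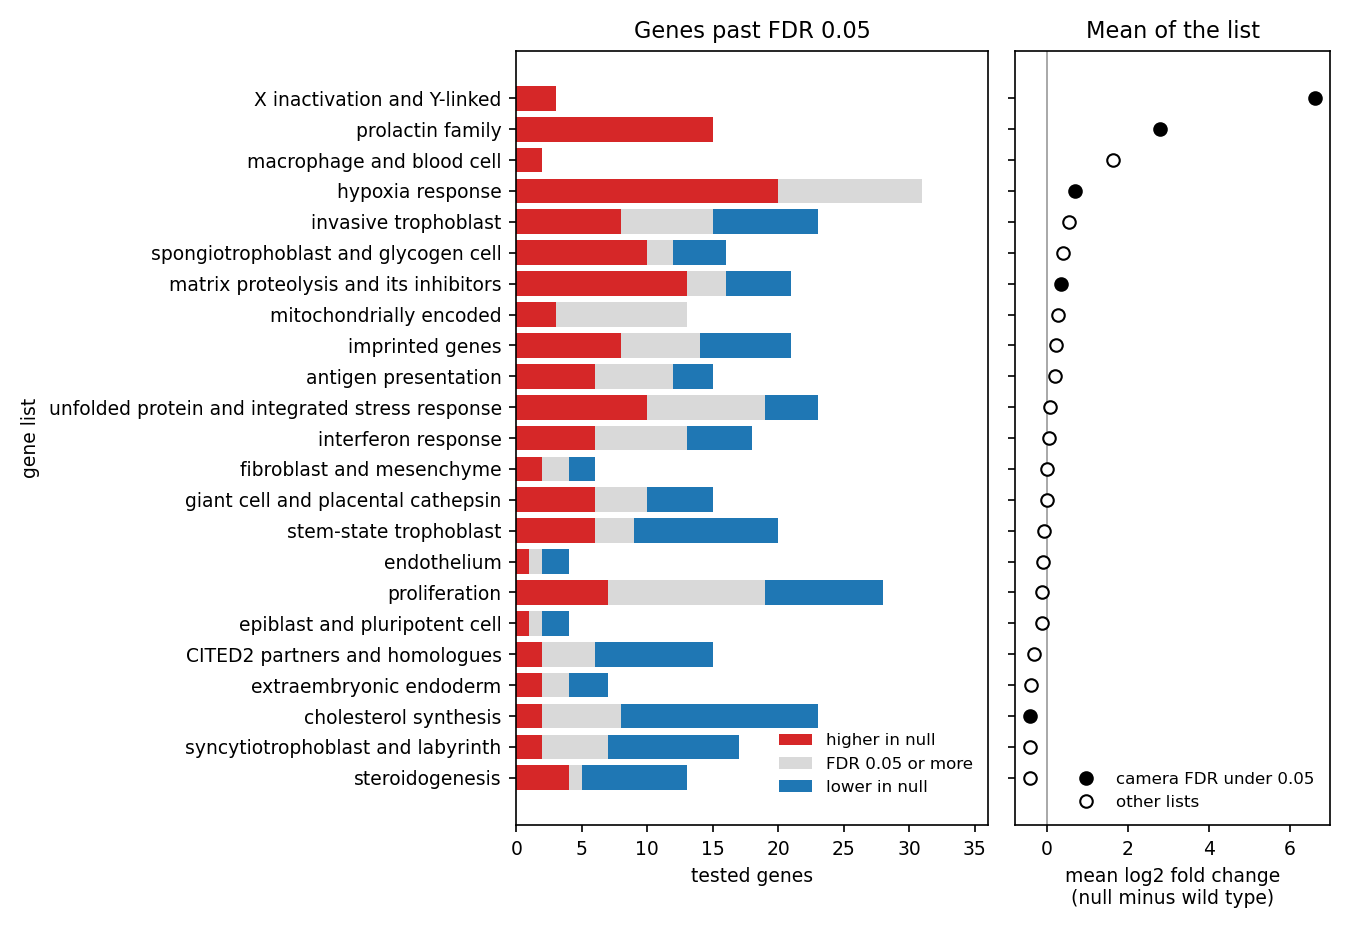
Left, the tested genes of each of 23 lists by direction and FDR over all genes (limma); right, the mean log2 fold change of the list (null minus wild type), filled where camera's adjusted p was under 0.05. The filled lists are the prolactin family at 2.80, hypoxia response at 0.68, matrix proteolysis at 0.34, cholesterol synthesis at -0.41 and the 3 genes of the Y-linked list, whose mean includes 2 genes read at 0 in wild type and is no bound; with an estimated correlation the adjusted p of each was 0.404 or more.

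Matrix proteolysis and its inhibitors, through which trophoblast opens the uterine matrix, had 13 genes higher, 5 lower and 3 not past the threshold among 21 tested. Adjusted over the list alone, 13 rose and 6 fell. The gelatinase Mmp9 fell from 147 ± 21.3 to 2.03 ± 0.478 RPKM (log2 fold change -6.13, SE 0.175, adjusted p = 7.56e-08), the widest fall among the genes named. Mmp12, the macrophage elastase that invasive trophoblast also makes, rose from 0.715 ± 0.117 to 5.44 ± 0.376 RPKM. Serpine1, the inhibitor of plasminogen activators, rose from 319.9 ± 22.4 to 859 ± 79.3 RPKM, and Adam9 fell by 0.54. Its mean was 0.34 and its median 0.56. Its camera adjusted p was 0.0472, and 0.752 with an estimated correlation. It was 0.0505 without wild type replicate B, 0.0637 without wild type replicate C and 0.082 without null replicate B. With all 6 libraries it also missed the threshold at a mean of 5 RPKM or more (mean 0.016, adjusted p = 0.2), by transcript (0.041, 0.177), with median-of-ratios scaling (0.0766), with limma-voom (0.0554) and after subtraction of the neighbourhood median (0.0569). Camera's adjusted p ranged from 0.0245 to 0.2 over the settings with a preset correlation and grouping by description. Fry placed the list upward with an adjusted p of 0.0041.

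Invasive trophoblast genes went both ways. Of 23 tested, 8 rose, 8 fell and 7 did not pass (9 and 8 adjusted over the list alone), with a mean of 0.55 and a median of 0.14. The camera adjusted p was 0.468. At a mean of 5 RPKM or more the list's mean turned to -0.063, and 3 of the 23 were prolactins of the segment from Prl5a2 to Mrs2. Cdkn1c, an imprinted inhibitor of the cell cycle, fell from 513 ± 19.5 to 276 ± 31.3 RPKM, and Doxl1, a diamine oxidase, fell from 2.38 ± 0.28 to 0.469 ± 0.194 RPKM. Prl7b1 and Pcdh12 were the members with the smallest p among those that rose.

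Spongiotrophoblast and glycogen cells form the junctional zone of the rat placenta and store glycogen. Of 16 tested genes, 10 rose, 4 fell and 2 did not pass, also when adjusted over the list alone. Pcdh12, a cadherin of glycogen cells, rose from 11.2 ± 0.386 to 42.6 ± 0.861 RPKM (log2 fold change 1.92), and Gbe1, which branches glycogen, rose from 8 ± 0.461 to 32 ± 2.43 RPKM (1.99). The noradrenaline transporter Slc6a2 fell from 9.7 ± 1.58 to 1.89 ± 0.198 RPKM. As a set it had a mean of 0.40, with a camera adjusted p of 0.146. The mean was 0.45 with no filter on low values (adjusted p = 0.0242) and -0.029 by transcript (0.643). Camera's adjusted p ranged from 0.0242 to 0.643 over the settings with a preset correlation and grouping by description, and was 0.752 with an estimated correlation.

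Syncytiotrophoblast and labyrinth genes serve exchange between mother and fetus. Of 17 tested, 2 rose, 10 fell and 5 did not pass, and 3 rose and 10 fell adjusted over the list alone. Gcm1, also a member, was too low to be tested, at 0.024 RPKM in wild type and 0.016 RPKM in null cells. Stra6, a retinol transporter, fell from 4.06 ± 0.685 to 0.318 ± 0.0621 RPKM, and Lifr fell from 72.6 ± 1.77 to 37 ± 1.68 RPKM. The efflux transporter Abcg2 rose from 2.76 ± 1.01 to 18.4 ± 1.81 RPKM. It lies in a stretch of 15 genes from Avl9 to Gadd45a with a median log2 fold change of 0.75. The lactate transporter Slc16a3 rose by 0.29. As a set the list had a mean of -0.43 and camera's adjusted p 0.146. The mean was -0.42 with no filter on low values (adjusted p = 0.0293) and -0.066 at a mean of 5 RPKM or more (0.622), the ends of the range of adjusted p over the same settings, and the adjusted p was 0.752 with an estimated correlation.

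The giant cell list holds genes of the large polyploid trophoblast cells and the placental cathepsins. Of 15 tested, 6 rose, 5 fell and 4 did not pass, also adjusted over the list alone. Its mean was -0.01 and its median 0.05, camera placed it upward and fry downward, and camera's adjusted p was 0.748. The cathepsin Cts8 rose from 4.33 ± 0.559 to 15.1 ± 1.33 RPKM and Lifr and Cyp17a1 fell, while Hand1, at 817 ± 47.4 and 741 ± 12.0 RPKM, did not pass (adjusted p = 0.14). Serpinb9d, a serine protease inhibitor of the trophoblast, rose from 36.2 ± 3.06 to 111 ± 9.19 RPKM. Cathepsins and the Serpinb9 family have close paralogs that may share reads.

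Stem-state genes went both ways. Of 20 tested, 6 rose, 11 fell and 3 did not pass, also adjusted over the list alone, with a mean of -0.09 and a camera adjusted p of 0.502. Fry, which asks whether the list moves on balance one way, placed it downward with an adjusted p of 0.000923. Eomes, a transcription factor of the stem state, rose from 2.38 ± 0.139 to 5.61 ± 0.62 RPKM, and Spry4 rose by 0.89. Gata2 fell from 148 ± 6.43 to 71.2 ± 6.21 RPKM, Tead4 by 0.69 and Cdx2 by 0.55. Proliferation genes also went both ways, with 7 higher, 9 lower and 12 not past the threshold among 28 tested, with 7 and 9 adjusted over the list alone and a camera adjusted p of 0.657. Mcm4 fell from 27.2 ± 3.71 to 9.23 ± 0.296 RPKM (log2 fold change -1.54) and Mcm3 by 0.93, and after the median change of the 50 nearest genes was subtracted they were at -0.73 and -0.59. Mcm6 rose by 0.51 and Pcna by 0.34, but after the same subtraction these were 0.079 and 0.047 and no longer passed (adjusted p = 0.313 and 0.614, the highest of their alternatives grouped by description).

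Among imprinted genes, which placental growth depends on, 8 of 21 tested rose, 7 fell and 6 did not pass (10 and 7 adjusted over the list alone), with a camera adjusted p of 0.657. Tssc4 rose from 0.0689 ± 0.0505 to 8.2 ± 0.823 RPKM and Ndn from 5.14 ± 0.781 to 20.4 ± 2.1 RPKM. Igf2r, the receptor that clears IGF2, fell from 45.9 ± 2.99 to 19.9 ± 1.78 RPKM, and Sfmbt2 fell by 0.70. The unfolded protein and integrated stress response list had 10 genes higher, 4 lower and 9 not past the threshold among 23 tested, also adjusted over the list alone, with a camera adjusted p of 0.345. The chaperones of the endoplasmic reticulum Hspa5 and Pdia6 rose from 541 ± 19.1 to 999 ± 65.5 RPKM and from 61.2 ± 0.756 to 116 ± 9.19 RPKM. Chac1 and Psat1, targets of the integrated stress response, had log2 fold changes of -1.67 and -0.84.

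Neither list of immune genes showed a common direction as a whole. Of 18 interferon response genes tested, 6 rose, 5 fell and 7 did not pass, also adjusted over the list alone. The list's mean was 0.03 and camera placed it upward with an adjusted p of 0.748, while fry placed it downward. Rsad2 and Oasl rose by 2.57 and 0.88, and Dtx3l and Parp9 fell, with log2 fold changes of -2.34 and -1.52. Of 15 antigen presentation genes, 6 rose, 3 fell and 6 did not pass, also adjusted over the list alone, with a camera adjusted p of 0.345. B2m, the light chain of class I molecules, rose from 40.6 ± 4.39 to 179.5 ± 30.9 RPKM and Tap1 by 0.66, whereas the proteasome activator Psme1 fell by 1.25 and Tapbp by 0.63. Of the class I heavy chain genes, RT1-A1, RT1-CE5, RT1-T24-4 and RT1-A2 rose by 0.67, 0.61, 0.58 and 0.53. RT1-CE10 and RT1-CE1 did not pass, at 0.25 and -0.035. Reads of the class I heavy chain genes may be shared among them.

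Genes of the greatest change were of several kinds. Maged1, an X-linked gene of the MAGE family, rose from 0.365 ± 0.0497 to 277 ± 26.4 RPKM (log2 fold change 9.22, SE 0.101, adjusted p = 6.63e-11). Dhrs4, Fuca2, H1f2 and Xlr4a were below 0.12 RPKM in wild type and at 14.6, 13.9, 31.1 and 19.3 RPKM in null cells. The heparanase Hpse rose from 3.21 ± 1.09 to 109 ± 6.05 RPKM, and Emb, Tpp1, Cd55 and Galnt6 rose by 5.05, 4.50, 4.50 and 4.49. Cd200 and Cd83, surface proteins that act on immune cells, fell from 62.3 ± 2.82 to 1.3 ± 0.176 RPKM and from 19.2 ± 1.1 to 0.317 ± 0.0619 RPKM. Crb3, a protein of epithelial polarity, fell by 4.99, the growth factor Nrtn by 3.75, and Col4a1, a basement membrane collagen, by 3.64. Flnc, Tnfsf9, Wnt7b, Septin4 and Vmac fell, with log2 fold changes of -3.55, -3.33, -2.86, -2.85 and -2.68. H1f2 has paralogs among the histones and Xlr4a in its own family, so reads of these may be shared.

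Markers of the Y chromosome differed. Of the 10 members of the X inactivation and Y-linked list, 6 were matched to a gene name. Xist, its member for X inactivation, was not among them, so the list gives nothing on X inactivation. The Y-linked Eif2s3y had 0 reads in each wild type library and 1316, 1419 and 1370 reads in null replicates A, B and C. Its null level of 27 ± 2.07 RPKM was at least 416-fold higher than the largest value that 3 reads give in a wild type library. The gene named Ddx3, a name that may stand for the Y-linked copy or for a copy of it elsewhere, had 0 reads in wild type and 16.6 ± 1.07 RPKM in null cells, at least 627-fold higher by the same floor. Floors of this kind cover counting error only. Kdm5d had 18, 15 and 21 reads in wild type and 677, 802 and 803 in null libraries, and rose by 4.46. Uba1y, a further Y-linked name, had 0 reads in each wild type library and 111, 154 and 194 reads in null replicates A, B and C. Ddx3y, Usp9y and Sry were near 0 in both genotypes. Ddx3y stood at 0.0078 RPKM in wild type and 0.0076 RPKM in null cells, and Usp9y and Sry were at 0 in wild type and at 0.038 and 0.0049 RPKM in null cells. Eif2s3y, Ddx3 and Kdm5d were the tested members of their list, and all 3 rose, also adjusted over the list alone. The list had a camera adjusted p of 7.21e-04 and an adjusted p of 0.404 with an estimated correlation. Fry placed it upward with an adjusted p of 3.83e-07.

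Markers of other cells the cultures could hold were few or moved both ways. Of the fibroblast and mesenchyme list 6 genes were tested, and 2 rose and 2 fell, also adjusted over the list alone, with a camera adjusted p of 0.748. Twist1 and Fbn1 rose by 0.91 and 1.10, Twist2 and Col5a1 fell, at -1.48 and -0.73. Of 4 endothelial genes 1 rose, Egfl7 at 1.03, and 2 fell, also adjusted over the list alone (camera adjusted p = 0.748). Cdh5 fell from 366 ± 4.14 to 199 ± 16.7 RPKM. Esam fell by 0.54 with an adjusted p of 0.04, which was 0.0981 and 0.118 without wild type replicates A and B and 0.0784 and 0.108 without null replicates A and C, with a log2 fold change of -0.33 without the last. It also missed the threshold with no filter (0.0661), without both C libraries (0.0677) and by transcript (0.121). Of the macrophage and blood cell list 2 genes were tested and both rose, also adjusted over the list alone. Cd68 rose from 6.71 ± 0.715 to 29.1 ± 0.621 RPKM and Itgb2 from 142 ± 11.2 to 316 ± 18.8 RPKM.

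Of 7 tested genes of the extraembryonic endoderm 2 rose and 3 fell, also adjusted over the list alone. The list's mean was -0.40 but its median 0.20, and camera placed it downward (adjusted p = 0.748). Lamb1, a laminin chain, fell from 24.3 ± 3.32 to 3.91 ± 0.818 RPKM, and Cited1 was a further member that fell. Sox7 rose by 0.73 and Hnf1b by 0.44, the latter with an adjusted p of 0.019, which was 0.0704 without null replicate B; without wild type replicate A Hnf1b was at 0.28. After subtraction of the neighbourhood median neither passed, at 0.46 (adjusted p = 0.0503) and 0.29 (adjusted p = 0.0938). Over their alternatives grouped by description the adjusted p ran from 0.0026 to 0.0503 for Sox7 and from 0.0049 to 0.0938 for Hnf1b. Of 4 epiblast genes 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.657), and the named ones changed little. Dppa4 fell by 0.31, and after subtraction of the neighbourhood median it stood at -0.090 (adjusted p = 0.355, from 0.0022 to 0.355 over its alternatives grouped by description). Klf4 rose by 0.22 with an adjusted p of 0.047, which lay between 0.0884 and 0.155 without wild type replicate A or B or null replicate B or C. Utf1 fell by 0.21 with an adjusted p of 0.0476, and without any single library except null replicate B it was between 0.0526 and 0.127, with a log2 fold change of -0.12 without null replicate C. After subtraction of the neighbourhood median Utf1 was at 0.0025 (adjusted p = 0.982), and it also missed the threshold with the replicate block (0.0561), median-of-ratios scaling (0.0846), limma-voom (0.0583), single transcripts (0.0606), no filter (0.078) and neither C library (0.247). Klf4 likewise missed it after the subtraction (0.0675), by transcript (0.0604) and with no filter (0.0775).

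Of the 13 mitochondrially encoded genes 3 rose and none fell, also adjusted over the list alone, with a mean of 0.26 and a camera adjusted p of 0.26. Mt-co1, a subunit of cytochrome oxidase, rose from 2703 ± 406 to 3851 ± 365 RPKM (log2 fold change 0.52, adjusted p = 0.00716) and Mt-co2 by 0.54. Without wild type replicate A the list's mean was 0.42 and its camera adjusted p 0.0411, and without wild type replicate C they were 0.071 and 0.81. The estimated correlation of these genes was 0.968, with an adjusted p of 0.861.

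Fold changes of neighbouring genes were alike. Across 9854 tested genes placed by the gene order of the GRCr8 assembly, the fold change of a gene correlated with that of the 10 genes around it at 0.363, against at most 0.0492 in 1000 shuffled orders. In 4 segments of 15 genes or more, 136 genes in all, the median changed by 0.5 or more on the log2 scale, against at most 1 such segment in each of 50 shuffled orders. The longest ran from Car2 to Tiparp with 91 genes and a median of 1.02, and 86 of these passed the threshold in that direction. The other segments had 15 genes each, the smallest size allowed. Since a shuffled order gave up to 1 segment, 1 of these could arise from a chance order. Outside the segments 6083 genes passed the threshold, or 62.6% of those placed, against 91.9% inside. The segments were chosen by these same fold changes, so a higher share inside them was set by the choice. They hold 1.38% of the placed genes, and the limit of 0.5 leaves out smaller regional shifts. Of the 267 X-linked genes tested, 61.8% passed, against 63.0% of the autosomal ones.

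**Figure D4:**
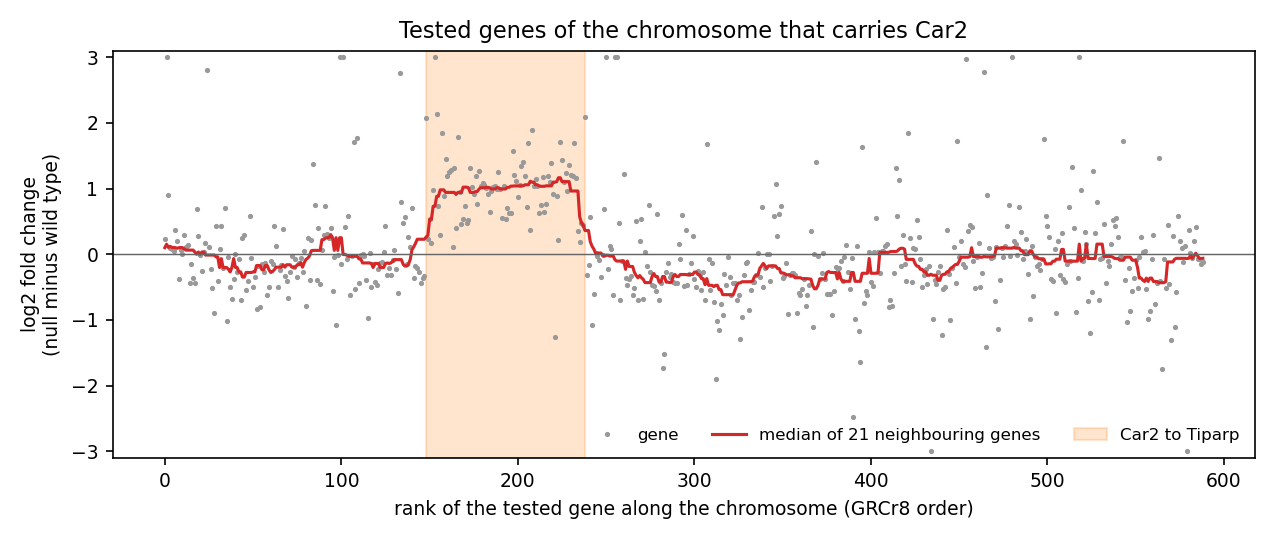
Log2 fold change (null minus wild type) of 589 tested genes in GRCr8 order along the chromosome that carries Car2 (points, 11 of them drawn at the limit of 3) with the median of 21 neighbouring genes (line). The shaded segment from Car2 to Tiparp has a median of 1.02, and the 20 genes before and after it have medians of -0.17 and -0.02.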

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

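The alternatives for single transcripts, median-of-ratios scaling, limma-voom and subtraction of the neighbourhood median were chosen after the data were seen, and the others before. The p-values rest on 3 libraries per genotype, and 3 reads in a 1000-base transcript are 0.0942 to 0.117 RPKM, so lower values are not told from 0. The count-based fits planned for a table of counts were not run, although whole reads could be recovered from the RPKM values; limma-voom was the one fit made on those reads. A test on uniquely mapped reads had also been planned, and the table has no column for it.

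Grouped by their titles, the C libraries left 0 genes past the threshold in limma, so 0 higher, 0 lower and 0 by 2-fold in either direction, with 52 at an unadjusted p under 0.05. Cited2 was then -1.62 (adjusted p = 0.975), and all 96 named genes lost their call; Pparg moved to -0.10 and Utf1 to 0.077. This grouping mixes the genotypes by construction. In the other alternatives Cited2 lay between -5.17 and -4.90 with adjusted p from 1.77e-12 to 5.20e-08, and 88 of the 96 named genes passed in each of them. Of 1417 values of named genes under these alternatives, 1385 kept their direction and side of the threshold, 31 no longer passed and 1 reversed, Utf1 at 0.0025 after the neighbourhood median was subtracted. That subtraction moved 15 of the 96 fold changes by over 1.5 times, among them Spry4 (0.54), Pdia6 (0.47), Twist1 (0.57) and Twist2 (-0.97), and 9 of the 15 still passed. A pseudocount of 1 did so for 16, all of which still passed, since it shrinks folds of genes low in 1 genotype. The replicate letters were not used as pairs. Correlations of the same letter across genotypes were weak, at 0.0965, 0.0437 and 0.131 for A, B and C, although each wild type library correlated best with the null library of its letter, so pairing is not excluded. As a block the letters gave 6975 genes, 6634 of them among the 6744.

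A 2-fold threshold left 1234 genes, 710 higher and 524 lower. With a pseudocount of 1, 816 passed both thresholds, 321 of them lower. With a mean of 5 RPKM or more, 555 of 7708 genes passed both, 322 higher and 233 lower, 554 of them among the 1234. Leaving out 1 library gave from 5855 genes without wild type replicate B to 6588 without null replicate C, which had its own lane. Limma-voom called 6844, of which 6592 were among the 6744, and median-of-ratios scaling 6811, of which 50.9% were higher against 46.3%. Subtraction of the neighbourhood median left 5374 genes of 9854, of which 4303 were among the 6744.

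The lists moved as follows; the cause was not tested unless stated. With an estimated correlation, which allows for genes that move together, the means were unchanged by construction and the adjusted p was 0.404 for the prolactin family (2.80), hypoxia response (0.68) and the Y-linked list (6.64), and 0.752 for cholesterol synthesis (-0.41) and matrix proteolysis (0.34). With a preset correlation and grouping by description, the prolactin family lay between 2.19 and 2.97 and hypoxia response between 0.54 and 0.73. Cholesterol synthesis was -0.40 (adjusted p = 0.136) at a mean of 5 RPKM or more. Matrix proteolysis was 0.016 at a mean of 5 RPKM or more (adjusted p = 0.2), 0.041 by transcript (0.177), 0.37 with median-of-ratios scaling (0.0766), 0.35 with limma-voom (0.0554), 0.34 after neighbourhood subtraction (0.0569) and 0.18 by title (0.107); camera's adjusted p ranged from 0.0245 to 0.2 with a preset correlation and grouping by description; without single libraries it lay between 0.28 and 0.41 (0.0261 to 0.082). The Y-linked list by title was 2.24 (adjusted p = 0.239); its means rest on genes at 0 and on the pseudocount.

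With no filter on low values, spongiotrophoblast reached 0.45 (adjusted p = 0.0242) and syncytiotrophoblast -0.42 (0.0293), and endothelium was 0.13, epiblast 0.10, interferon response -0.10 and stem-state 0.019, of other direction than before. The mean reversed at 5 RPKM or more for imprinted genes (-0.085) and invasive trophoblast (-0.063); by transcript for imprinted genes (-0.13), spongiotrophoblast (-0.029) and fibroblast (-0.13); with a pseudocount of 1 for fibroblast (-0.036) and giant cell (0.059); with median-of-ratios scaling for giant cell (0.025); after neighbourhood subtraction for fibroblast (-0.13) and epiblast (0.037); and by title for endothelium (0.059), epiblast (0.023) and mitochondrial genes (-0.040). Without single libraries, fibroblast lay between -0.050 and 0.055, giant cell between -0.046 and 0.047, interferon response between -0.021 and 0.081, and mitochondrial genes between 0.071 and 0.42, where the set test passed without wild type replicate A (adjusted p = 0.0411). Fry, which asks a different question, passed for CITED2 partners (-0.32, adjusted p = 0.000923), stem-state (-0.089, 0.000923), spongiotrophoblast (0.40, 0.0015), steroidogenesis (-0.43, 0.0018), syncytiotrophoblast (-0.43, 0.0041), invasive trophoblast (0.55, 0.0041), extraembryonic endoderm (-0.40, 0.0115), the unfolded protein response (0.071, 0.0135) and fibroblast (0.0064, 0.048), whose means stay as they were.

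The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 6744 genes and 1234 by 2-fold, 1 of the 10 with as many, and the highest other split gave 0 of each; limma's unadjusted p under 0.05 was reached by 7204 genes in the real split and by 16 to 108 in the others.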

Other observations

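All tests of explanations in this part were chosen after the results were seen. The genes in this paragraph were picked after their values were seen, and no set of them was tested. Igf2, the imprinted growth factor of the placenta, fell from 123 ± 3.83 to 28.99 ± 8.26 RPKM (log2 fold change -2.12), while its clearing receptor Igf2r also fell. Plau, the urokinase, rose from 44.6 ± 0.335 to 218 ± 72.4 RPKM, and its receptor Plaur rose by 0.75. The other activator Plat rose by 0.56, and of the inhibitors Serpine1 rose by 1.42 and Serpine2 fell by 0.52. Flt1, a receptor for VEGF, rose from 1.02 ± 0.0508 to 5.004 ± 0.548 RPKM. Among genes of glycogen, Pygl and Ugp2 rose by 1.27 and 0.49 and Gys1 did not pass (-0.15, adjusted p = 0.162). Cyp11a1, which starts steroid synthesis, fell from 198 ± 24.5 to 96.9 ± 15.4 RPKM.

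Some genes were read in 1 genotype alone. With 100 reads or more in each library of 1 genotype and 3 or fewer in each of the other, 16 genes were read in null cells, among them Ddx3, Eif2s3y, Uba1y, Fuca2, H1f2, Dhrs4, Gng2 and Zfp612, and 2 in wild type, Zfp512 and LOC100911295. LOC100911713, the transcript that passes in the authors' deposited table, followed the titles of the C libraries and not their descriptions: it stood at 10.2, 8.68 and 0 RPKM in wild type replicates A, B and C and at 0.308, 0.0824 and 4.92 RPKM in null replicates A, B and C. Fold change was not related to transcript length across 10861 genes, which are not independent (Spearman's rho -0.0079).

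Neighbouring genes shifted together. The correlation of 0.363 with the 10 genes around a gene, against at most 0.0492 in 1000 shuffled orders, argues against a chance order of genes. Medians of 50-gene windows spread 5.73 times as widely between the genotypes (0.26) as in the most divergent comparison within a genotype (0.0454), which argues against differences between single libraries. Of 45 genes left out when the Car2 to Tiparp segment was found, 97.8% shared its sign, with a median of 0.96 against 1.03 in the genes that found it, and this is consistent with a copy number difference behind the shared shift, though not behind each gene's own fold (quartiles 0.64 and 1.25), as a hypothesis, since RNA alone does not count copies; regulation of the whole stretch stays open, and so does loss of CITED2 itself, since the labels separate genotype from cell line in 0 libraries. Of 21 chromosomes, 16 had a median beyond that of 1000 random gene sets, from -0.45 on the chromosome of Igf2bp2 to 0.37 on that of H3f3a.

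Reads of Y-linked genes appeared in the null libraries; reads of the X-linked copy placed on Eif2s3y are argued against by 0 such reads in each wild type library, where Eif2s3 stood at 67.2 RPKM. Male fibroblasts in the null cultures, which the conditioned medium would make a candidate source, are argued against by their abundant genes Col1a1, Col3a1, Dcn, Lum and Postn, whose highest null mean was 0.123 RPKM. The 6 tested members of the fibroblast list were read in both genotypes, and 2 rose and 2 fell in null cells. Pdgfra, 1 of the 6, stood at 19.4 RPKM in wild type and 22.4 RPKM in null cells. The argument thus rests on the genes named first. The number of Y-chromosome genes with 100 reads or more in each null library and 10 times the wild type was 3 (Eif2s3y, Kdm5d and Uba1y), consistent with null cells that are male and wild type cells without a Y chromosome. The other 6 of 9 Y-chromosome names did not meet this rule, among them Ddx3y, which stood at 0.0076 RPKM in null and 0.0078 RPKM in wild type, and Usp9y and Sry, at 0.038 and 0.0049 RPKM in null, so the reading rests on 3 genes. Sex of the cell lines may then differ with genotype in all 6 libraries, and no library separates them.

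The prolactin family was higher in null cells, and a copy number difference of a stretch that reaches past the family is argued against by the 20 tested genes beside it, with a median of 0.16 (quartiles -0.23 and 0.57) against 2.72 for all 15 tested members. A copy number difference of the family's stretch as the whole cause is argued against by the members, since 10 of the 14 lay more than 3 SE from their median of 2.97, and 5 of the 8 at 1 RPKM or more in wild type, where the pseudocount matters less, from theirs of 2.31 (Prl2a1 at 1.38, SE 0.0999, and Prl4a1 at 3.83, SE 0.108), while a part in the rise stays open, with 0 other tested genes between the first and last member. Reads exchanged among members cannot raise the family's sum, which rose 5.53-fold, from at most 1278 RPKM in a wild type library to at least 6280 RPKM in a null one. More spongiotrophoblast and glycogen cells alone would raise their other markers, of which 10 of 16 rose and 4 fell. Of all 10861 tested genes 3123 rose and 3621 fell, so some falls among 16 genes would be found in most lists. The count therefore does not decide for or against this explanation. Loss of CITED2 itself, sex and other differences between the lines cannot be told apart here, since the labels separate genotype from line in 0 libraries.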
